A study of Arabidopsis thaliana with 6 samples.

How the data were processed

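RNA from floral apices (shoot tips that have begun to make flowers) of long-day grown Arabidopsis thaliana was hybridised to a single-colour oligonucleotide array. Each transcript is represented on it by a set of short probes. There were 6 arrays in 3 groups of 2: plants carrying the empty plasmid as control, plants overexpressing the microRNA miR156b, and plants overexpressing miR164b. Groups were taken from the labels of each sample. The labels do not say whether the 2 arrays of a group, lettered a and b, came from separate plants or pools of plants, so p-values measure only the spread between these samples, which may be technical.

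The deposited values are 1 intensity per probe set and array on a linear scale, as the authors processed them. The software, background correction and summary method behind them are not given in the sources used here. The mean intensity after trimming 2% at each end was 200.01 on every array, so the deposited arrays were already scaled to a common level and no further scaling was applied. Because of that scaling, a change shared by most transcripts would not be visible. The number of arrays limits the precision, with 3 residual degrees of freedom in the fit plus 2.42 from the prior.

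The array holds 22810 probe sets, of which 64 are controls and 22746 were tested. Gene names came from the platform annotation, which can be old. It named 13513 of the tested probe sets by 1 gene, 503 by several genes, and left 8730 unnamed here. Of the 1-gene probe sets, 13436 matched a locus of the TAIR10.1 gene table, which was used for names only, and no coordinates are given because the build behind the array annotation is not given in the sources used here. No gene is named from a probe set with several genes or none. Probe sets of 1 gene were tested separately.

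The values were converted to log2(intensity + 16), so fold changes are on that scale and understate the change of transcripts with low signal. Limma 3.58.1 (lmFit and eBayes in R 4.3.3) was fitted to all 6 arrays with 3 group means, without covariates, and gave 3 contrasts: each overexpressor against the empty vector, and miR156b against miR164b overexpressors. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and 0.05 was the threshold. All adjusted p-values of single genes are from this limma fit. The same code was tested on simulated data built from the levels and spreads of all 22746 probe sets for the miR156b comparison. It recovered 14.9% of changes of 0.5 on the log2 scale, 97.0% of changes of 1 and 100% of changes of 2. Of its 148 calls, 7 were false. The changes were placed only in probe sets above a set vector signal, with independent errors, so the recovered shares do not cover dim probe sets. They numbered 67, 67 and 66 by size, against 2283 calls in the real comparison, so the adjusted threshold was stricter than in the data. The errors were normal with the spreads of the fit itself, so the few false calls do not test that assumption.

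Before the data were examined, 25 gene lists with 362 entries were fixed. They cover the SPL targets of miR156, SPL genes without a miR156 site, the NAC targets of miR164, NAC genes without a miR164 site, targets of other microRNAs, floral meristem identity and flowering time, floral organ identity and patterning, shoot meristem, organ boundary, organ polarity, the mitotic cell cycle, DNA replication, and early auxin response. Others mark tissues or states that dissected apices could hold: photosynthesis, anther and tapetum, seed, secondary wall, anthocyanin and flavonoid, trichome, senescence, salicylate defence, jasmonate and wounding, heat shock, cold and dehydration, and the circadian clock. In 6 lists no member was named by the annotation, namely both microRNA target lists, the NAC genes without a site, seed, secondary wall and salicylate defence, and these lists are not analysed here. In 8 lists only 1 or 2 members were named, so only their values are given. The other 11 lists were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists within a contrast, with an estimated correlation and with fry beside it. With the estimated correlation, camera uses only the 3 residual degrees of freedom, so few lists can pass. Fry asks whether the members change at all, not whether they move apart from other probe sets. The minimum of 3 named members was chosen after seeing how many were named. A planned comparison of transcripts with and without predicted microRNA sites needs transcript sequences, which were not used here.

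The genes named in the text followed a rule fixed before the data were examined. For each overexpressor against the vector it takes the measured members of that microRNA's target list, then the 8 largest rises and 8 largest falls among probe sets past the threshold that name 1 gene and have both arrays on the same side of both control arrays. To these it adds up to 4 members past the threshold from each other list, and the precursor genes of both microRNAs, which the annotation does not name. Between the overexpressors it takes the 5 largest differences in each direction. Up to 2 unnamed probe sets per direction are given by identifier, and members of lists that did not pass are given by value.

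Alternative settings fixed beforehand were a second quantile normalization, a shift of the arrays to a common median, removal of the dimmest 40% of probe sets (13647 left), a fit on only the 2 groups compared, an intensity trend with a robust prior, the array letter as a block, pseudocounts of 1 and 64, a minimum change of 2-fold, and leaving out each array in turn. Because both overexpressors are compared with the same vector arrays, 100 simulated data sets of unchanged groups against shared controls gave the covariance of fold changes to be had without any effect. The covariance was also computed with 1 vector array given to each overexpressor, a test chosen after the data were seen.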

Results

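Transcript levels in floral apices were measured on 6 arrays, 2 each from empty-vector control plants, miR156b overexpressors and miR164b overexpressors. Both microRNAs are small regulatory RNAs: miR156 represses SPL transcription factors, which promote the change from juvenile to adult growth and flowering, and miR164 represses a group of NAC transcription factors that set organ boundaries. The comparisons ask which transcripts of the floral apex differ when either microRNA is overexpressed. No SPL gene with a miR156 site and no NAC gene with a miR164 site was named by the annotation, so these targets are not analysed here. Log2 signals of the 2 arrays of a group correlated at 0.994 (vector), 0.993 (miR156b) and 0.994 (miR164b) across probe sets, and those of arrays from different groups at 0.975 to 0.982. The median difference between the 2 arrays of a group was 0.10 (vector), 0.12 (miR156b) and 0.10 (miR164b) on the log2 scale. Median signals lay between 87.5 and 90. The 3′ to 5′ signal ratio of the GAPDH control transcript, a sign of RNA quality, was 1.12 and 1.15 on the vector arrays and 0.896 to 0.930 on the 4 overexpressor arrays. A second GAPDH set gave 1.17 and 1.18 against 1.08 to 1.25, 1 actin set 9.28 and 9.001 against 7.54 to 10.97, and another actin set 1.68 and 1.72 against 1.23 to 1.55. Vector and overexpressor arrays thus separated in 2 of these 4 ratios. The array also holds ubiquitin control sets, for which no ratio was computed.

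In miR156b overexpressors, 3 of the 4 named anther and tapetum genes rose (camera adjusted p = 1.19e-05; adjusted p = 0.0952 with an estimated correlation). Among the 8 largest named rises was AT5G62080, a gene on none of the lists. It went from a signal of 8.45 ± 2.90 in the vector to 1600 ± 88.7 (SD, n = 2 each), a change of 6.05 ± 0.10 on the log2 scale (SE, limma adjusted p = 4.72e-05). AMS, a transcription factor needed for the tapetum that feeds the pollen, rose by 3.95 ± 0.11 (adjusted p = 0.000263), and AT5G07230 (A9, a tapetum transcript) by 4.65 ± 0.15 (adjusted p = 0.00035). The 4 named photosynthesis genes and the 4 named anthocyanin genes rose by smaller amounts, and AGL42, AGL24 and FD, regulators of flowering time, fell (adjusted p = 0.0952 with an estimated correlation for each of these lists).

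Of the 4 named genes of the anther and tapetum list, 3 rose (AMS, A9 and NZZ, the last by 1.05 ± 0.08), while EMS1 gave 0.18 ± 0.11. The list was higher than other probe sets (camera adjusted p = 1.19e-05, mean log2 fold change 2.46), with an adjusted p = 0.0952 with an estimated correlation, and 3 passed when adjusted over the list alone. Other large rises were AT3G52130 (5.44 ± 0.08), LCR66, a cysteine-rich peptide gene (4.89 ± 0.07), AT1G44970, a peroxidase gene (4.80 ± 0.13), AT4G29980 (4.80 ± 0.12), AT3G07450 (4.58 ± 0.06) and AT1G33430 (4.42 ± 0.22). Signals of these 6 genes were at most 54.8 in the vector mean and at least 742.8 in the miR156b mean. AT5G62080, AT3G52130, AMS, A9, LCR66 and AT4G29980 were near background in the vector, with mean signals below the pseudocount of 16. The sizes and order of their rises are therefore uncertain (AT5G62080 and AT3G52130 gave 7.44 and 7.40 with a pseudocount of 1).

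All 4 named photosynthesis genes rose in miR156b overexpressors, and 4 passed when adjusted over the list alone. SBPASE, an enzyme of the Calvin cycle, rose by 0.88 ± 0.07, PRK, another, by 0.86 ± 0.07, RCA, the activase of Rubisco, by 0.67 ± 0.06, and LHCB4.1, a light-harvesting protein, by 0.57 ± 0.07 (camera adjusted p = 1.19e-05 for the list; adjusted p = 0.0952 with an estimated correlation). The 4 named genes of the anthocyanin and flavonoid list also rose, UGT75C1 (AT4G14090) by 0.92 ± 0.18 and UF3GT by 0.71 ± 0.07. AT5MAT rose by 0.67 ± 0.13 and DFR, the reductase that commits flavonoids to anthocyanin, by 0.61 ± 0.11. The camera adjusted p was 0.000313, the adjusted p = 0.0952 with an estimated correlation, and 4 passed when adjusted over the list alone. These groups were higher on the same arrays that had the higher AMS, A9 and NZZ signals, and the lower 3′ to 5′ ratio of 1 GAPDH and 1 actin set. By design, any gene called against the vector, here and below, differs on these same arrays. That alone is no sign of a link to the anther genes or the ratios, nor does it exclude one. The cold genes COR15A (0.93 ± 0.10) and COR47 (0.93 ± 0.07), the 2 named members of their list, rose as well. SAG29, a sugar transporter gene on the senescence list, rose by 1.43 ± 0.09, and SIM, an inhibitor of cell division on the trichome list, by 0.39 ± 0.08.

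Of the floral meristem and flowering time list, 3 of 4 named genes fell, on the same arrays that had the higher AMS, A9 and NZZ signals and the lower ratio of 1 GAPDH and 1 actin set. AGL42 fell by 1.05 ± 0.08, AGL24 fell by 0.74 ± 0.13 and FD, the partner of the florigen FT at the apex, fell by 0.62 ± 0.09. GI had a log2 fold change of -0.25 ± 0.07 (adjusted p = 0.0783). The camera adjusted p of the list was 0.000778, with an adjusted p = 0.0952 with an estimated correlation, and 4 passed when adjusted over the list alone. The floral organ list had 0 of 4 named genes past the threshold (camera adjusted p = 0.0707, mean log2 fold change -0.41). Of the 8 largest named falls, AT4G00870, a bHLH factor, fell by 1.98 ± 0.18 (limma adjusted p = 0.00571). AT1G48750, of the lipid transfer protein family, fell by 1.88 ± 0.08 (adjusted p = 0.000842) and AT3G26590 fell by 1.72 ± 0.11. MT1C, a metallothionein whose near-identical copies make the probe set uncertain, fell by 1.71 ± 0.07. The remaining falls were MSRB5 (-1.58 ± 0.12), AT3G59270 (-1.56 ± 0.15), AT2G37900 (-1.52 ± 0.12) and AT4G37900 (-1.52 ± 0.08). YUC4, an auxin synthesis gene, fell by 0.42 ± 0.07 as the only early auxin list member past the threshold (list adjusted p = 0.745). Of the 20 largest falls of all probe sets, 13 were unnamed, among them 247718_at, from a mean signal of 307.7 to 2.05 (-4.16 ± 0.09), and 247717_at (-3.38 ± 0.16). Of the 20 largest rises 5 were unnamed, including 245622_at (4.46 ± 0.18) and 261096_at (4.13 ± 0.27). Because 247718_at was near background in miR156b overexpressors, and 245622_at and 261096_at in the vector, the sizes of these changes are uncertain.

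The remaining tested lists were not called: targets of other microRNAs (camera adjusted p = 0.514, 0 of 5 named genes past the threshold), the mitotic cell cycle (0.514, 0 of 3), organ polarity (0.773, 0 of 4), trichome (0.181, 1 of 3) and senescence (0.076, 1 of 4). Organ polarity had a mean of 0.04 and a median of -0.03. Single named members of other lists had log2 fold changes of -0.04 ± 0.12 (SPL16, without a miR156 site), -0.52 ± 0.18 (CLV3, shoot meristem), -0.25 ± 0.12 (LAS, organ boundary), -0.22 ± 0.07 (PRL, DNA replication), 0.13 ± 0.22 (PDF1.2, jasmonate) and 0.32 ± 0.16 (HSP22.0, heat shock), none of them past the threshold. CCL of the clock list gave 0.30 ± 0.08 (adjusted p = 0.084).

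Altogether 2283 of 22746 probe sets (10%) differed between miR156b overexpressors and the vector in the limma fit, 1256 higher and 1027 lower, and 301 of them by at least 2-fold, 215 higher and 86 lower. The count was 359 without vector array a, 340 without vector array b, 413 and 545 without miR156b arrays a and b, 1013 without either miR164b array, and 1011 with a pseudocount of 1. The share of calls that were higher was 55.0%, and 48.7% without the dimmest probe sets. With any 1 of the 6 arrays left out, 3 anther genes, 2 to 4 photosynthesis genes, 0 to 1 anthocyanin genes and 1 to 2 flowering genes passed, COR15A lost its call with 3 of the arrays left out in turn, SIM and YUC4 with each of the 6, and AT3G59270 without vector array b (adjusted p = 0.056).

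**Figure D1:**
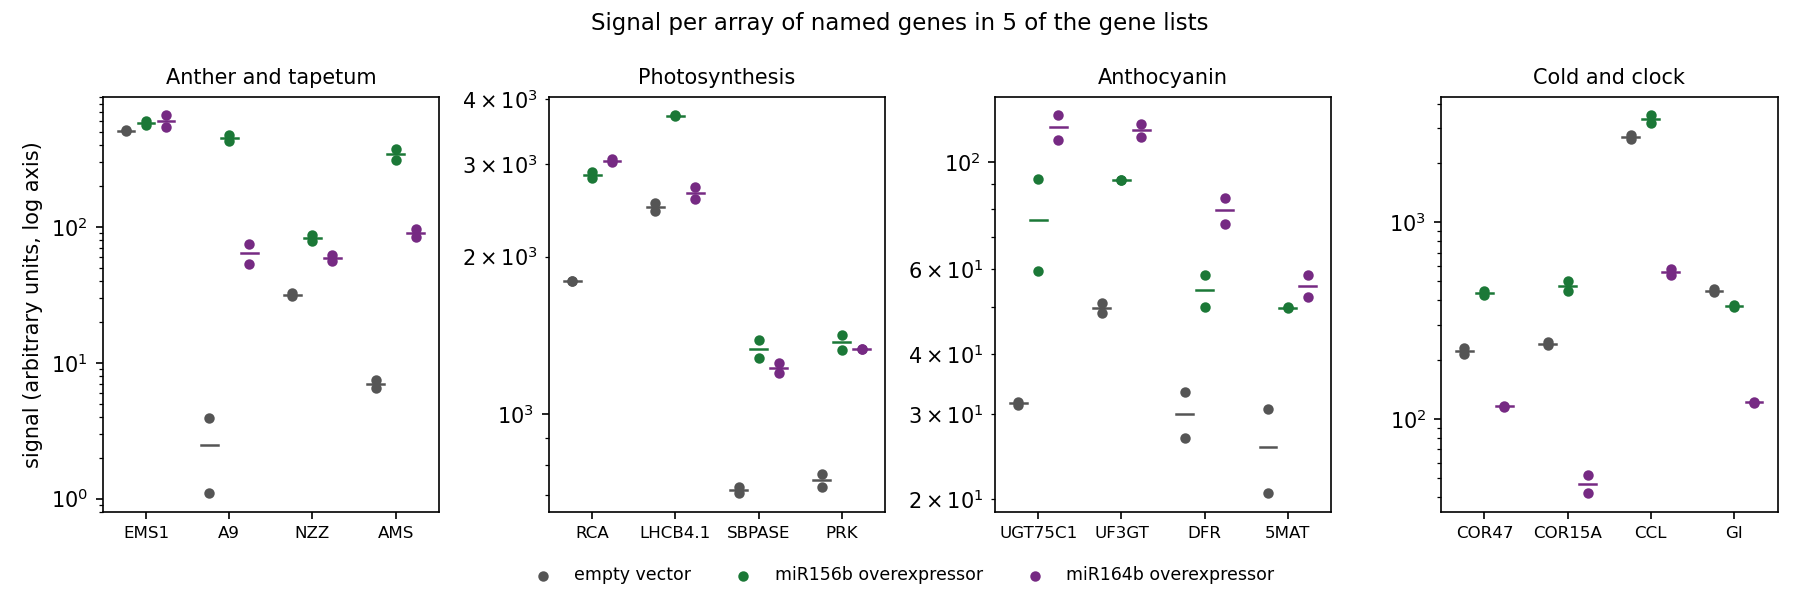
Signal per array (arbitrary units, log axis) of the named genes of the anther and tapetum, photosynthesis, anthocyanin, and cold and clock lists, with each point 1 array, each short line the mean of 2, and colour the group. AMS lay at a mean of 6.95 in the vector, 90.4 in miR164b and 341 in miR156b overexpressors, while COR15A was highest in miR156b (474) and lowest in miR164b (46.9).

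In miR164b overexpressors, both named genes of the cold list and both of the clock list fell; with 2 members each, these lists were not tested. The same arrays had the higher AMS, A9 and NZZ signals and the lower ratio of 1 GAPDH and 1 actin set. So had the miR156b arrays, where both cold genes were higher than in the vector and both clock genes were not called. COR27, a cold-induced regulator of the clock, had a mean signal of 410 ± 1.84 in the vector and 8.40 ± 5.09 in miR164b overexpressors (SD, n = 2 each) and fell by 4.14 ± 0.15 on the log2 scale (SE, limma adjusted p = 0.000304). GI and CCL, the 2 named members of the clock list, fell by 1.76 ± 0.07 and 2.24 ± 0.08 (adjusted p = 0.000338 and 0.000328). Of the named genes, 3 of 4 on the anther list, 3 of 4 on the photosynthesis list and 4 of 4 on the anthocyanin list rose (adjusted p = 0.105 with an estimated correlation for each list).

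The 2 named cold genes fell in miR164b overexpressors, of which COR15A fell by 2.03 ± 0.10 and COR47 fell by 0.84 ± 0.07. Of the 8 largest named falls, CCL alone is on a list, and no enrichment was tested among the others. AT4G30650, a low-temperature and salt responsive gene, fell by 3.92 ± 0.07, AT4G33980 (COR28) fell by 2.64 ± 0.12 and COR15B fell by 2.25 ± 0.08, beside COR27. AT1G56300, a DnaJ chaperone gene, fell by 4.49 ± 0.10, more than COR27 on this scale. With a pseudocount of 1 COR27 fell more (-5.57, against -5.08 for AT1G56300), and its signal in miR164b overexpressors, like that of AT4G33980, was near background, so the sizes of these falls are uncertain. MT1C (-2.38 ± 0.07, uncertain as above) and AT4G32340 (-2.37 ± 0.10) fell as well. Unnamed probe sets made up 12 of the 20 largest falls, led by 267461_at (-5.02 ± 0.17) and 249741_at (-3.71 ± 0.21).

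All 4 named anthocyanin genes rose in miR164b overexpressors, UGT75C1 by 1.49 ± 0.18, DFR by 1.05 ± 0.11, UF3GT by 1.01 ± 0.07 and AT5MAT by 0.79 ± 0.13 (camera adjusted p = 8.95e-05; adjusted p = 0.105 with an estimated correlation). Adjusted over the list alone, 4 passed. The anther and tapetum list had 3 of 4 named genes up, AMS by 2.21 ± 0.11, NZZ by 0.66 ± 0.08 and A9 from a mean signal of 2.50 to 63.95. EMS1 gave 0.22 ± 0.11 (camera adjusted p = 0.000143; adjusted p = 0.105 with an estimated correlation). Adjusted over the list alone, 3 passed. Of the photosynthesis genes 3 of 4 rose, PRK by 0.82 ± 0.07, SBPASE by 0.76 ± 0.07 and RCA by 0.76 ± 0.06, while LHCB4.1 gave 0.08 ± 0.07 (camera adjusted p = 0.000323; adjusted p = 0.105 with an estimated correlation). Also 3 passed when adjusted over the list alone. All of these rises lay on the arrays with the lower ratio of 1 GAPDH and 1 actin set. On this scale the 8 largest named rises were AT5G62080 (4.17 ± 0.10), AT1G44970 (from a mean signal of 54.8 to 1184), AT3G52130 (3.62 ± 0.08), AT4G29980 (3.33 ± 0.12), AT1G33430 (3.10 ± 0.22), LCR66 (2.74 ± 0.07), AT3G07450 (2.73 ± 0.06) and AT5G41890 (2.46 ± 0.16), of which the first 7 were also among the 8 largest in miR156b overexpressors. Of these, AT5G62080, AT3G52130, AT4G29980, LCR66 and AT5G41890 were near background in the vector, as were AMS and A9, so the sizes and order of their rises are uncertain. SAG29 rose by 0.99 ± 0.09 and SIM by 0.49 ± 0.08. The unnamed probe sets 261569_at (4.63 ± 0.14) and 258497_at (3.88 ± 0.10) rose most of all unnamed ones, and 9 of the 20 largest rises were unnamed.

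Named members of the floral organ, auxin and flowering lists fell on the same arrays that had the higher AMS, A9 and NZZ signals and the lower ratio of 1 GAPDH and 1 actin set. That holds by design for any gene called against the vector. Of the floral organ list, SPT, a carpel factor, fell by 0.90 ± 0.09 and UFO, needed for petal and stamen identity, fell by 1.08 ± 0.24, which was 2 of 4 named genes (camera adjusted p = 0.024; adjusted p = 0.158 with an estimated correlation; 3 past when adjusted over the list alone). The early auxin list had 3 of 4 named genes down. GH3.5 (WES1) fell by 0.68 ± 0.08, GH3.3 fell by 0.53 ± 0.09 and YUC4 fell by 0.38 ± 0.07 (camera adjusted p = 0.0145; adjusted p = 0.155 with an estimated correlation; 3 past when adjusted over the list alone). The flowering time list also passed (camera adjusted p = 0.0147; adjusted p = 0.155 with an estimated correlation), with GI, a clock gene, as its 1 of 4 genes past the threshold and 2 when adjusted over the list alone. LAS, a regulator of lateral shoot formation and the 1 named organ boundary gene, fell by 0.71 ± 0.12 (adjusted p = 0.0231). SPL16 (AT1G76580), a relative of the miR156 targets that lacks a site, fell by 0.66 ± 0.12 (adjusted p = 0.0268), and APS4, a sulphur assimilation gene targeted by another microRNA, fell by 0.58 ± 0.11 (adjusted p = 0.0319).

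The lists of other microRNA targets (camera adjusted p = 0.845, 1 of 5 named genes past the threshold, mean -0.05 and median 0.07), organ polarity (0.845, 0 of 4, mean 0.01 and median -0.04), the mitotic cell cycle (0.845, 0 of 3), trichome (0.371, 1 of 3) and senescence (0.371, 1 of 4) were not called. CLV3 (0.27 ± 0.18), PRL (0.03 ± 0.07), PDF1.2 (0.11 ± 0.22) and HSP22.0 (0.29 ± 0.16) did not pass the threshold.

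In total 2375 probe sets (10.4%) differed between miR164b overexpressors and the vector, 1325 higher and 1050 lower, and 479 by at least 2-fold, 281 higher and 198 lower. The count was 907 and 958 without vector arrays a and b, 756 and 786 without miR164b arrays a and b, and 1494 with a pseudocount of 1; the floral organ list gave 0.0684 without vector array a and 0.0793 without the dimmest probe sets, the auxin list 0.052 without miR164b array b. With any 1 of the 6 arrays left out, 2 to 3 anther genes, 3 photosynthesis genes, 1 to 3 anthocyanin genes, 0 to 2 auxin genes, 1 to 2 floral organ genes and both cold and both clock genes passed, while SPL16 and SIM lost their calls with 4 of the arrays left out in turn, and LAS and APS4 with 5.

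Compared directly, the 5 largest named differences on this scale towards miR156b overexpressors were genes that rose in those plants and fell in miR164b overexpressors. COR27 was higher in miR156b than in miR164b overexpressors by 5.14 ± 0.15, AT1G56300 by 4.97 ± 0.10, AT4G30650 by 4.32 ± 0.07, AT4G33980 by 3.90 ± 0.12 and COR15B by 3.65 ± 0.08 (log2, SE, n = 2 each; limma adjusted p between 8.97e-05 and 0.000133). COR27 and AT4G33980 were near background in miR164b overexpressors, so the sizes and order of these differences are uncertain. Against the vector, COR27 (adjusted p = 0.019), COR15B (0.00156), AT4G30650 (0.0252), AT4G33980 (0.0068) and AT1G56300 (0.0441) were all higher in miR156b overexpressors. The anther list was higher in miR156b overexpressors, with 3 of 4 named genes past the threshold and also 3 when adjusted over the list alone. A9 differed by 2.55 ± 0.15, AMS by 1.74 ± 0.11 and NZZ by 0.39 ± 0.08. Its camera adjusted p was 0.017, with an adjusted p = 0.486 with an estimated correlation, 0.0649 with a pseudocount of 1 and 0.0514 without miR164b array b.

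Higher in miR164b overexpressors were AT5G23970 (-2.96 ± 0.13 for miR156b over miR164b), AT4G23680 (-2.77 ± 0.08) and HYH, a light-signalling factor (-2.75 ± 0.14). So were AT1G48750 (-2.44 ± 0.08) and CHIL, a chalcone isomerase-like gene of flavonoid synthesis (-2.38 ± 0.13). AT5G23970 and HYH were near background in miR156b overexpressors, so the sizes and order of these differences are uncertain. AGL42 was lower in miR156b than in miR164b overexpressors (-1.04 ± 0.08, adjusted p = 0.0019), while AGL24 (-0.44 ± 0.13, adjusted p = 0.0909) and FD (-0.21 ± 0.09, adjusted p = 0.212) did not differ past the threshold. GI, CCL, COR15A, COR47, GH3.3, GH3.5 and SPT were higher in miR156b overexpressors, with adjusted p from 0.000157 to 0.00698. UFO (adjusted p = 0.343) and LAS (0.0637) did not pass. Of the 4 anthocyanin genes UF3GT alone did (-0.30 ± 0.07, adjusted p = 0.0464). The 10 other tested lists had camera adjusted p between 0.123 and 0.894 in this contrast, and organ polarity had a mean of 0.04, a median of -0.10 and a downward camera direction. In all, 3281 probe sets differed between the overexpressors, 1575 higher and 1706 lower in miR156b, and 585 by at least 2-fold. Which side held more turned with the setting: 48.0% were higher in miR156b here, 52.7% with a common median, and 51.7% and 51.0% without miR164b arrays a and b. The count was 1624 and 1946 without miR156b arrays a and b, 1145 and 1201 without miR164b arrays a and b, and 2169 with a pseudocount of 1.

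**Figure D2:**
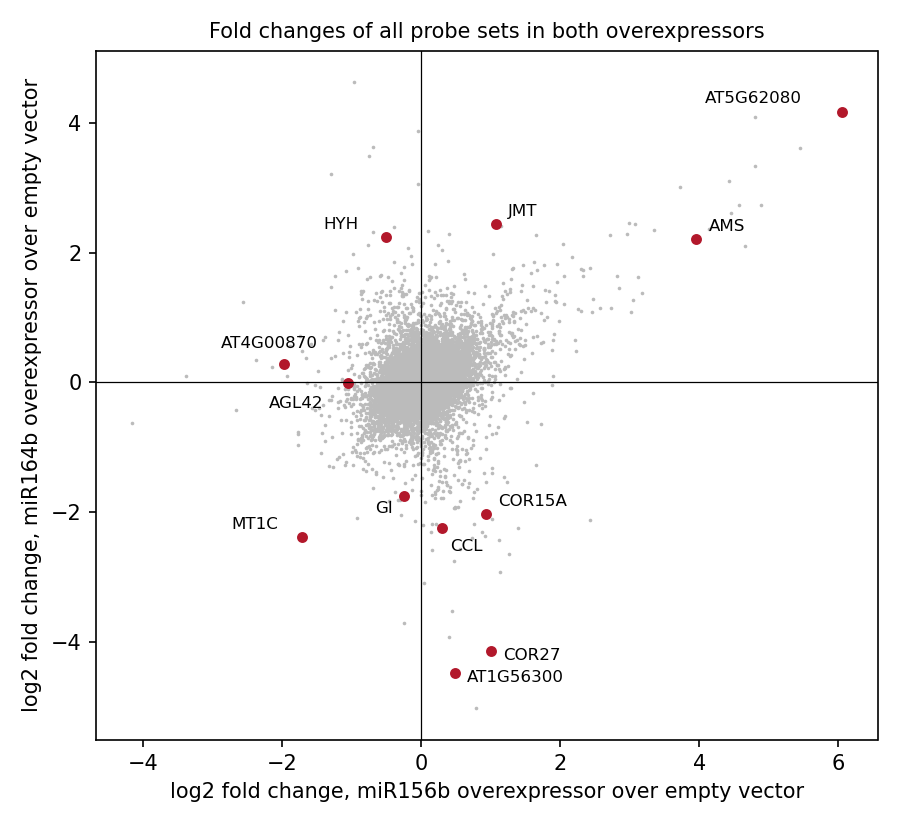
Log2 fold change over the empty vector of each of the 22746 probe sets in miR156b (horizontal axis) and miR164b overexpressors (vertical axis), with 12 genes marked. AT5G62080 and AMS lie high on both axes (6.05 and 4.17, 3.95 and 2.21), while COR27 and AT1G56300 lie far below 0 in miR164b (-4.14 and -4.49).

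Both overexpressors shared 443 probe sets higher and 227 lower than the vector, where independent lists would share 73.2 and 47.4, and 242 went in opposite directions (118 for independent lists). AT5G62080, AMS and the anthocyanin genes were among those higher in both, and COR15A and COR47 among those in opposite directions. The log2 fold changes correlated at 0.343 across probe sets, which are not independent replicates, and simulated groups with no effect correlated at 0.4997 because they share the vector arrays. The covariance was 0.0402, against 0.0117 in simulation, a difference of 0.0285. With 1 vector array given to each overexpressor, so that no control was shared, the covariance was 0.0292 and 0.0282 for the 2 ways of giving them out. The counts of shared calls were made with both vector arrays, so part of their excess may come from the shared arrays. The shared calls in the same direction numbered 670 and became 158 and 164 without vector arrays a and b, 205 and 238 without miR156b arrays a and b, 186 and 185 without miR164b arrays a and b, and 331 with a pseudocount of 1. The opposite calls became 30 and 29 without vector arrays a and b, 66 and 74 without miR156b arrays a and b, 88 and 92 without miR164b arrays a and b, and 98 with a pseudocount of 1. Of 1371 probe sets past the threshold in miR156b overexpressors alone, 847 differed in the direct contrast, and of 1463 in miR164b overexpressors alone, 1042 did.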

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

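The tests of explanations in this part, the control probe sets and the split of the vector arrays were chosen after the results were seen, while the list tests and the simulations of shared vector arrays were planned. Probe sets of the poly-A control transcripts, which can be added to RNA before labelling and were left out of the comparisons, stood above both vector arrays on 2 arrays. Their median signal over the vector mean (24 probe sets) was 1.12 on miR156b array a and 1.46 on miR164b array a, against 0.944 and 0.947 on the b arrays of those groups. The hybridisation controls (18 probe sets) were at 0.901 and 0.956 in miR156b and 0.728 and 0.821 in miR164b overexpressors. The 25S ribosomal RNA probe set ranged from 131 on miR156b array a to 3900.5 on vector array b and did not follow the groups.

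Of the 4 named anther and tapetum genes, AMS, A9 and NZZ were higher in both overexpressors and EMS1 was called in neither (the list's adjusted p = 0.0952 and 0.105 with an estimated correlation). A single scaling factor per array would move the list and the other probe sets together. Instead the list's median log2 fold change lay above that of all probe sets by 2.53 in miR156b and 1.40 in miR164b overexpressors. The list test had already shown such a difference. The SE of these values (0.07 and 0.09) comes from the limma SEs of the middle members alone. It leaves out the spread between members, from 0.18 (EMS1) to 4.65 (A9) in miR156b and 0.22 (EMS1) to 2.21 (AMS) in miR164b overexpressors. If signal is proportional to transcript, a larger share of 1 kind of anther-bearing bud predicts that each gene rises in miR164b by the same fraction of its rise in miR156b. The fractions were 0.138 for A9, 0.250 for AMS and 0.543 for NZZ, the highest 3.94 times the lowest. Their ranges over the arrays did not overlap (at most 0.173 for A9 and at least 0.422 for NZZ). The ranges rest on 2 arrays per group, whose spread may be technical. Signal may also not be proportional to transcript at the low vector signals of A9 and NZZ (means 2.50 and 31.65). Within these limits the ranges argue against such a share as the whole cause for these 3 genes. Of the 7 largest named rises outside the list, 4 had ranges that overlapped that of AMS, as a share predicts (AT5G62080, AT3G52130, AT4G29980 and AT3G07450). LCR66, AT1G44970 and AT1G33430 did not. Among the 4, however, AT4G29980 (at least 0.291) lay above the ranges of the others (at most 0.283). Apices of another stage or make-up could still account for the 3 genes above both vector arrays in miR164b, and because the labels give no stage this cannot be told apart from an effect of the microRNAs.

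The 2 named clock genes and the 2 named cold genes were lower in miR164b overexpressors. These arrays also had the higher AMS, A9 and NZZ signals, as did the miR156b arrays. Colder growth of the vector plants alone would put COR15A and COR47 below the vector in miR156b overexpressors too, but their mean there was 0.93 ± 0.06 (log2, SE). Harvest at another time of day could account for the median of -2.00 of GI and CCL, and since the labels give no time it cannot be told apart from an effect of miR164b. Different growth or harvest of each group, rather than of the vector alone, also stays open.

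The fold changes of both overexpressors covaried more than chance in the shared vector arrays gave: the covariance was 0.0402, against at most 0.0126 in 100 simulations, and 0.0292 and 0.0282 where each overexpressor was compared with 1 vector array of its own. A real difference of the vector samples, in stage or handling, would add to both comparisons in the same way and stays open, as do effects shared by the microRNAs.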

How the results depend on the processing

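All alternatives were planned except the families (also with probe sets averaged by gene), the anther list median under other scalings, the counts of list members, the expected covariances and the split of the vector arrays, which were chosen after seeing the data. For the miR156b comparison, 2283 calls became 3463 without the dimmest probe sets, 1013 on only the 2 groups compared, 1169 with the array letter as a block, 1011 with a pseudocount of 1, 301 at 2-fold or more, and 340 to 1013 with 1 array left out. The block concerns arrays that share only a letter (deviations correlated at 0.0120, 0.00956 and -0.0720), and it kept the counts of the 2 other comparisons within 1.5 times and each list call, but ended 7 of 83 gene calls; shared calls were not counted with it. For miR164b, 2375 became 1494 with a pseudocount of 1, 479 at 2-fold or more and 756 to 1979 with 1 array left out, and for the direct contrast 3281 became 2169, 585 and 1145 to 2406. Of the 359 and 340 calls without vector arrays a and b in the miR156b comparison, 340 and 325 were among the 2283. Fewer arrays leave fewer degrees of freedom, and a lone array is assumed to vary like the other groups; for the other settings the cause was not tested. Each of the 11 list calls passed with fry (adjusted p from 0.00029 to 0.022). Fry asks only whether members change, so a list with called members can pass without moving apart from other probe sets. With an estimated correlation no list passed. Adjusted p was then 0.0952 for the 4 called lists in miR156b, and 0.486 for the anther list between overexpressors. In miR164b it was 0.105 (anther, photosynthesis, anthocyanin), 0.155 (flowering, auxin) and 0.158 (floral organ). This version of camera has only the 3 residual degrees of freedom. The unadjusted camera p of the anther list in miR156b went from 1.68e-06 to 0.0166 with it. Not passing therefore cannot tell correlated genes from few degrees of freedom. The floral organ list in miR164b gave 0.0793 without dim probe sets and 0.0134 to 0.0684 with 1 array left out, the auxin list 0.0074 to 0.052, and the anther list between overexpressors 0.00435 to 0.0514, and 0.0649 with a pseudocount of 1. Fry gave the flowering list between overexpressors the opposite direction (0.0175, against 0.531 with camera), and the cause was not tested. Of lists not called, 9 more passed with fry, and the floral organ list in miR156b passed (0.0287) on only the 2 groups compared and without either miR164b array. The covariance was 0.151 and 0.0144 with pseudocounts of 1 and 64, where shared arrays alone would give 0.0718 and 0.00333. Shared calls in the same direction numbered 331 with a pseudocount of 1 and 158 to 238 with 1 array left out, instead of 670. Opposite calls numbered 445 without dim probe sets, 98 and 392 with pseudocounts of 1 and 64, and 29 to 92 with 1 array left out, instead of 242. Of 1159 alternatives for 83 gene and comparison pairs, 1023 kept the call, 136 lost it and 0 reversed. Leaving out 1 array ended the call of 24 pairs on at least 1 array, with adjusted p up to 0.195, and of 59 on none. The 83 pairs had been chosen as past the threshold in these data, so the lack of reversals does not test their direction. Genes whose signal is near background, as A9 in the vector, have the least certain fold changes.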

Other observations

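The family tests here were chosen after the data were seen, on 30 families of at least 8 members sharing a symbol prefix. As a family, the SWEET sugar transporter genes were higher in miR164b overexpressors, with 6 of 14 past the threshold and 0 down. The camera adjusted p was 0.00114 over the families, and 0.561 with an estimated correlation and its 3 residual degrees of freedom. These arrays also had the higher AMS, A9 and NZZ signals and the lower 3′ to 5′ ratio of 1 GAPDH and 1 actin set. That holds by design for any gene called in this comparison. SAG29, the sugar transporter gene named above, does not share the prefix and was not counted. SWEET8, needed for the pollen wall, rose by 1.94 ± 0.09, SWEET10 by 1.35 ± 0.09, SWEET7 by 1.15 ± 0.17, SWEET3 by 1.09 ± 0.13, SWEET2 by 0.71 ± 0.07 and SWEET1 by 0.57 ± 0.07 (log2, SE). SWEET3 and SWEET7 were near background in the vector (mean signals 14.7 and 11.45), so the sizes of their rises in both overexpressors are uncertain. In miR156b overexpressors the family did not pass (camera adjusted p = 0.102), with SWEET3 (3.02 ± 0.13), SWEET7 (2.57 ± 0.17), SWEET8 (2.17 ± 0.09) and SWEET1 (0.39 ± 0.07) up and SWEET17, which fell by 0.34 ± 0.06. With 1 array left out 3 of the family were up each time, and 0 were down except without miR156b array a (1). The count in miR164b was 6 under both other scalings, 4 and 5 without vector arrays a and b, 7 without either miR156b array, and 3 without either miR164b array. SWEET10 was higher in miR164b than in miR156b overexpressors (-1.04 ± 0.09 for miR156b over miR164b, limma adjusted p = 0.00247), and SWEET3 lower (1.93 ± 0.13, adjusted p = 0.00116).

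Of 15 probe sets for 8 mitochondrial NAD genes, 4 were lower past the threshold in miR164b overexpressors (camera adjusted p = 0.0385; adjusted p = 0.561 with an estimated correlation; mean -0.28), and 4 under both other scalings. With the probe sets of each gene averaged, 2 of 8 genes passed and the family was not called (camera adjusted p = 0.224). These arrays also had the higher AMS, A9 and NZZ signals and the lower 3′ to 5′ ratio of 1 GAPDH and 1 actin set, as for any gene called here. No more than 3 passed with 1 array left out, and 0 without vector array a. In miR156b overexpressors the mean was -0.24 (camera adjusted p = 0.102), and no family other than SWEET and NAD passed in either comparison; with probe sets averaged by gene SWEET alone did, in miR164b overexpressors (camera adjusted p = 0.00116; adjusted p = 0.561 with an estimated correlation).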
